A study of Mus musculus with 24 samples.

How the data were processed

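Epithelial cells were isolated from the distal colon of 12 mice aged 21 days, 4 each of Ptpn2 knockout (KO), heterozygote (HET) and wild type (WT), per the labels. The tissue was shaken in a cold cell recovery solution to release the epithelium, and total RNA was extracted on columns, per the labels' protocols, which describe no sorting step. RNA of each mouse was hybridised to 2 NanoString nCounter mouse panels with added custom targets, one for autoimmune profiling and one for cancer pathways, which makes 24 samples. The nCounter assay counts fluorescent barcodes bound to target RNA without amplification. The panels were normalised separately and joined in nSolver 4.0, per the series' design text. The mice came from 3 littermate groups that held 1, 1 and 2 mice of each genotype. All 4 KO mice were female, while WT and HET each had 3 females and 1 male, so sex is partly tied to genotype.

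The values used are those of the authors' 2 deposited tables, one for KO against WT and one for HET against WT, each with 1398 targets. Per the file headers, the authors deposited a log2 fold change with its standard error for every target. The deposited tables also give the fold change as a ratio with 95% limits. A p-value, a false discovery rate and the kind of regression follow for every target, per the file headers. The regression was named lm.nb for 967 targets, loglinear for 298 and Wald for 133. Another 12 columns of values carry names that match no sample label, so they were not used, and no value per mouse enters any result. The depth of each sample is therefore unknown here. Precision is carried by the deposited standard errors, whose median for KO against WT was 0.27 on the log2 scale for lm.nb, 0.16 for loglinear and 0.44 for Wald targets.

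The deposited tables were checked for how their columns relate, with a tolerance of 5 percent. All 1398 p-values in each deposited table follow from the log2 fold change divided by its standard error with 7 degrees of freedom, or 6 for Wald targets. Genotype alone would leave 9 in 12 mice, so the authors' model spent 2 more than genotype needs, or 3 more for Wald targets. The terms of that model are not stated in the sources used here. A term for the 3 littermate groups beside genotype would also leave 7, but whether it was fitted is unknown. The deposited false discovery rate equals the Benjamini-Yekutieli adjustment of the deposited p-values for all 1398 targets. The deposited limits of the ratios span 1.96 standard errors on each side for all 1398 targets of each table, so they are narrower than limits from a t distribution with few degrees of freedom.

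The plan written before the data were examined was a limma fit on values per mouse. No column could be assigned to a mouse, so the authors' p-values took its place. They were adjusted here by Benjamini-Hochberg over 1398 targets, and a target rose or fell when its adjusted p was under 0.05. KO against HET was computed here from the difference of the deposited log2 fold changes. Its standard error was the root of the mean of both deposited variances, and it was read against a t distribution with 7 degrees of freedom, or 6 for Wald targets. That form is exact for equal groups with a pooled spread and approximate otherwise. Because the authors' p-values come from a small number of mice, they rest on the model and not on an exact test.

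Lists of genes were fixed before the data were examined, 34 in number, and 30 with at least 4 measured targets were tested. The test was limma's camera on signed z values from the p-values, 2-sided, with a preset correlation between targets of 0.01 and Benjamini-Hochberg adjustment over the 30 lists. The correlation between targets could not be estimated and limma's fry was not run, since both need values per mouse. Preset correlations of 0.05 and 0.5 were run in their place. Camera compares a list with all other targets. A list called higher or lower is so relative to those targets, which need not be a change from the reference genotype. Member counts are given over all targets and adjusted over the list alone. Targets eligible for naming were, by a rule written before the data were examined, the 10 risen and the 10 fallen with the largest change in KO against WT and the 5 risen and the 5 fallen with the smallest adjusted p in the other comparisons. Where none passed in a direction, the 2 with the smallest p were named. Each list added up to 4 members past the threshold with the smallest p in KO against WT, or the 1 member with the smallest p, which made 83 targets in all. The planned condition that every KO mouse lie beyond every WT mouse could not be applied. Targets singled out after their values were seen are named as such.

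Ptpn2 itself is not analysed here, so the genotype labels have no check from its transcript. Symbols were taken from the gene table for 1354 targets, from the RefSeq identifier of the probe for 42, by letter case for 1, and from the file for 1. A second probe was kept apart for 14 genes, which leaves 1384 symbols. Coordinates are from GENCODE M21 on GRCm38.

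The calling steps were tested on 1398 simulated targets for KO against WT, of which 200 were changed. At 2-fold, 55% of changed targets were called, and at 4-fold 91%. Of the calls, 3.31% were unchanged targets. None of 200 lists drawn from unchanged targets reached p under 0.05 in camera. The test takes its spread from all targets, the changed ones included. It therefore does not show how camera behaves on lists with changed or correlated members.

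Of the alternatives planned before the data were examined, a minimum absolute log2 fold change of 1 was run, and second probes were kept apart throughout. Alternatives chosen after seeing the data were Benjamini-Yekutieli, Bonferroni and no adjustment, standard errors moderated with limma, fold changes centred on their median, 1 probe per gene, and leaving out Wald targets. For lists they were the other preset correlations, ranks, and the log2 fold change as camera's statistic. Fits that need values per mouse were not run: other normalisations, a low-value filter, pseudocounts, leaving out each mouse, fits with 2 genotypes, other variance models, sex or littermate terms, and other splits of the mice. R 4.3.3 with limma 3.58.1 was used, and Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.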

Results

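RNA from isolated epithelial cells of the distal colon was measured in 12 littermate mice aged 21 days, 4 each of KO, HET and WT for Ptpn2. Ptpn2 encodes a tyrosine phosphatase that removes phosphate from JAK kinases and STAT proteins and so restrains signalling by interferons and other cytokines. The 2 nCounter panels together gave 1398 targets, chosen by their makers for immune and cancer pathways with custom additions, so the targets are not a sample of all genes. All values come from the authors' deposited table of each comparison, and depth per sample is unknown here. Ptpn2 itself is not analysed here.

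The comparison of KO with WT asks what the loss of Ptpn2 changes in the epithelial cell preparation. No sorting step is described, so the changes are not assigned to a cell type. The chemokines Ccl2, Ccl7 and Ccl8, which draw monocytes, and Ccl5, Cxcl9 and Cxcl10, which draw T cells, were higher in KO. Lists of genes induced by interferon and of the machinery that presents antigen on MHC molecules were higher as sets. The receptor Lgr5, which marks intestinal stem cells, was lower, and so were Atoh1, the transcription factor that commits cells to the secretory lineage, and Dclk1, a marker of tuft cells. The T cell and NK list and the macrophage and dendritic list were also higher as sets in KO. Single targets passed for 9 of 27 and 4 of 12 of their members. The macrophage and dendritic list did not pass at either of the higher preset correlations.

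In KO, 155 targets rose and 45 fell of 1398 at an adjusted p under 0.05. By the false discovery rate the authors' deposited table itself gives, which uses the stricter Benjamini-Yekutieli adjustment, 3 targets pass, Ccl5, Ccl8 and Gzma. The median log2 fold change over all targets in the authors' deposited table was 0.14, and after subtracting it 103 targets rose and 75 fell. The share of called targets that rose was 77.5% before that step and 57.9% after it, a shift that subtracting a positive median brings by construction. With a minimum absolute log2 fold change of 1 it was 85.1%, from 126 risen and 22 fallen targets. Named targets that lose their call after centring are Jak2, Vil1, Dusp5, Dusp6, Ccnd2, Ccne1, Mcm4, Tlr2, Stat2, Mrc1, Nfkb2, Il4ra and Tyrobp.

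**Figure D1:**
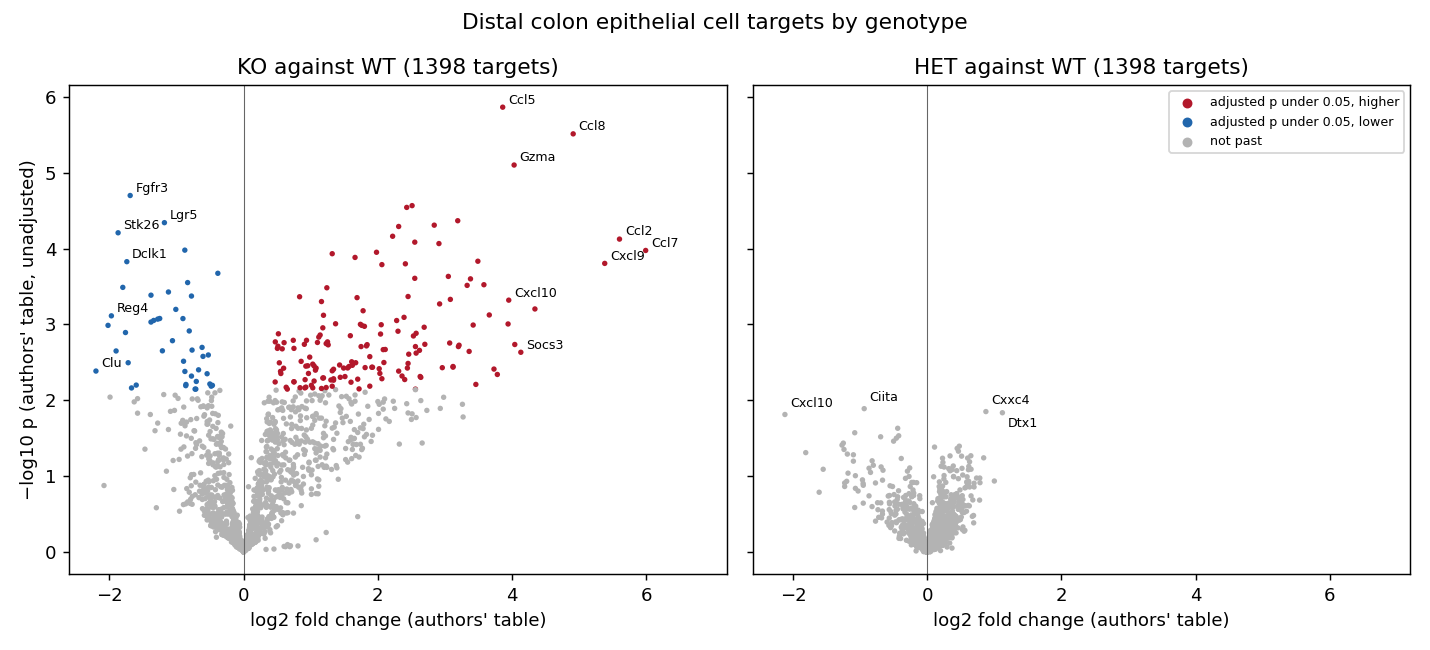
Log2 fold change of KO against WT (horizontal axis) and −log10 of the unadjusted p (vertical axis) for 1398 targets, with HET against WT plotted the same way. In KO, 155 targets rose and 45 fell, and in HET 0 passed.

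The largest rise was that of Ccl7 (chromosome 11, 82045712 to 82047525, GRCm38), a monocyte chemokine, with a log2 fold change in the authors' deposited table of 5.99 (SE 0.77, adjusted p 0.00861), a ratio of 63.8 with 95% limits of 22.5 and 181. Its neighbours Ccl2 (chromosome 11, 82035571 to 82037453) and Ccl8 (chromosome 11, 82115185 to 82116799) rose by 5.60 (SE 0.68, adjusted p 0.00802) and 4.91 (SE 0.37, adjusted p 0.00215) in the authors' deposited table. Cxcl9, which interferon gamma induces, is a ligand of the chemokine receptor Cxcr3 on T cells. Cxcl9 rose by 5.38 (SE 0.73, adjusted p 0.00911) on the log2 scale of the authors' deposited table. Cxcl10, a ligand of the same receptor, rose by 3.95 (SE 0.65, adjusted p 0.0159) on that scale. Ccl5, which draws T cells, had the smallest adjusted p, 0.00192, with a log2 fold change in the authors' deposited table of 3.86 (SE 0.26), a ratio of 14.5. The other targets among the 10 largest rises were Ifi44l, Socs3, Nos2, Gzma and Ifi44, with log2 fold changes in the authors' deposited table of 3.94 to 4.34. Socs3 encodes a feedback inhibitor of STAT3 signalling, Nos2 the inducible nitric oxide synthase, and Gzma a protease of cytotoxic lymphocytes.

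Of the fallen targets, Clu, a secreted chaperone, had the largest change, with a log2 fold change in the authors' deposited table of −2.20 (SE 0.53, adjusted p 0.0386). Reg4, a lectin of deep crypt secretory cells, changed by −1.97 (SE 0.35, adjusted p 0.0216), and Dclk1 by −1.74 (SE 0.24, adjusted p 0.00912) on the log2 scale of the authors' deposited table. Fgfr3 (chromosome 5, 33721674 to 33737068), a fibroblast growth factor receptor, had the smallest adjusted p among them, 0.00669, with a log2 fold change in the authors' deposited table of −1.69 (SE 0.17). The Wnt receptor Fzd9, the gluconeogenic enzyme Pck1, the kinases Stk26 and Mapk15, the protein kinase A subunit Prkar2b and the transcription factor Mycn complete the 10, between −2.02 and −1.72 in the authors' deposited table.

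The interferon response list was the most clearly shifted. Of its 35 targets, 25 rose, 1 fell and 9 did not pass, and adjusted over the list alone 32 rose and 1 fell. The median log2 fold change of this list in the authors' deposited table was 2.40, and camera gave an adjusted p of 2.13e-08. The exception was Ifi27, an interferon-induced mitochondrial protein, which fell by 1.12 on the log2 scale of the authors' deposited table (adjusted p 0.0149). The MHC class I list had 6 of 12 targets risen and none fallen (9 adjusted over the list alone, camera adjusted p 0.00646). Among them were B2m, the invariant light chain, at 1.98 (SE 0.26), H2-K1 at 1.76 (SE 0.33), and the immunoproteasome subunit Psmb9 at 2.05 (SE 0.38) on the log2 scale of the authors' deposited table. MHC class II genes, which are mostly active in professional antigen-presenting cells and switched on in epithelium by interferon gamma through Ciita, had 7 of 9 targets risen (8 adjusted over the list alone), with a median log2 fold change of 3.08 in the authors' deposited table and a camera adjusted p of 0.000131. Ciita (chromosome 16, 10480059 to 10528418) rose by 2.51 (SE 0.26, adjusted p 0.00669), H2-Eb1 by 3.49 (SE 0.47), H2-DMa by 3.38 (SE 0.50) and Cd74, the invariant chain, by 3.33 (SE 0.51) in the authors' deposited table.

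Leukocyte markers moved beside these lists. All 27 T cell and NK targets had a positive fold change, 9 rose and 18 did not pass (17 rose adjusted over the list alone), with a median log2 fold change of 1.57 in the authors' deposited table and a camera adjusted p of 4.09e-05. Gzma had a log2 fold change of 4.03, Gzmb 2.43, the T cell receptor component Cd3g 2.55 and the interleukin receptor chain Il2rb 2.45 in the authors' deposited table. In the macrophage and dendritic list 4 of 12 rose (9 adjusted over the list alone, camera adjusted p 0.0386), among them the complement subunits C1qb at 2.04 and C1qa at 1.84 in the authors' deposited table. Of 7 pan-leukocyte targets 3 rose, Itgal, Itgb2 and Ptprc (4 adjusted over the list alone), without the list passing (camera adjusted p 0.284). In the B and plasma cell list 1 of 14 rose, Prdm1, which T cells also express (camera adjusted p 0.118). The neutrophil and mast cell list had 1 of 16 fallen, the receptor Kit, which crypt secretory cells also carry, and no rise (0 adjusted over the list alone, camera adjusted p 0.671).

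Cytokine and signalling lists rose in part, beside that rise in leukocyte markers. Of 39 inflammatory cytokine and chemokine targets 11 rose and 28 did not pass (14 adjusted over the list alone), with a camera adjusted p of 0.0176. In the IL-6, IL-22 and STAT3 list 3 of 12 rose (5 adjusted over the list alone, camera adjusted p 0.0176), Socs3, the kinase Pim1 at 1.83 and the receptor chain Il4ra at 0.93 on the log2 scale of the authors' deposited table. The JAK-STAT list had 5 of 26 risen both over all targets and adjusted over the list alone (camera adjusted p 0.0383). They include Jak2 at 0.47 (SE 0.10), Stat2 at 1.51 (SE 0.37) and the feedback inhibitor Socs1 at 3.20 (SE 0.67) in the authors' deposited table. Lists share members, so their results are not independent. In another list as well are 6 of 26 JAK-STAT, 8 of 12 IL-6, IL-22 and STAT3, 8 of 16 antimicrobial and all 5 Paneth targets. In the NF-kB list 5 of 26 rose (11 rose and 1 fell adjusted over the list alone, camera adjusted p 0.0302). The adhesion molecule Icam1 changed by 2.69, the NF-kB inhibitors Nfkbie by 1.24 and Tnfaip3 by 1.62, and the subunit Nfkb2 by 0.92 in the authors' deposited table. Of 25 inflammasome and cell death targets, 7 rose and 1 fell (14 and 1 adjusted over the list alone) while the list did not pass (camera adjusted p 0.0798). Il1b and the death ligand Tnfsf10 rose by 1.80 and 2.62, and the inflammasome adaptor Pycard fell by 0.38 on the log2 scale of the authors' deposited table. Antimicrobial defence had 3 of 16 risen (4 and 1 fallen adjusted over the list alone, camera adjusted p 0.507), among them the bacterial sensors Nod2 at 2.46 and Tlr2 at 1.07 in the authors' deposited table.

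Epithelial lineage targets were few and fell in part. Of 10 stem cell targets only Lgr5 (chromosome 10, 115450311 to 115587780) passed, here and adjusted over the list alone, with a log2 fold change of −1.18 (SE 0.13, adjusted p 0.00716) in the authors' deposited table. The stem cell list was lower than the other targets by camera (adjusted p 0.0284). Its median log2 fold change in the authors' deposited table was −0.19, with 7 targets negative and 3 positive. Of 4 goblet cell targets 1 fell, Atoh1 at −0.88 (SE 0.11, adjusted p 0.00861) in the authors' deposited table, and 3 fell adjusted over the list alone, which adds Muc2, the main secreted mucin, and Spdef, a regulator of goblet cell maturation (camera adjusted p 0.033). Over all targets Muc2 (adjusted p 0.0939) and Spdef (adjusted p 0.0635), singled out after their values were seen, did not pass. Of 4 absorptive colonocyte targets Vil1, a microvillus protein, rose by 0.50 and the Notch effector Hes1 fell by 0.72 on the log2 scale of the authors' deposited table, without the list passing (camera adjusted p 0.854). In the Paneth list 1 of 5 rose, Nod2 (camera adjusted p 0.671). Lists with fewer than 4 targets were not tested: of 3 tuft targets Dclk1 fell, of 3 epithelial targets Vil1 rose (2 rose and 1 fell adjusted over the list alone), of 2 adhesion targets Cdh1 had the smaller p without being past the threshold (1 rose adjusted over the list alone), as was the case for Chga, the only enteroendocrine target.

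Cell cycle and growth pathways showed few calls. In the proliferation list 4 of 31 rose, also adjusted over the list alone (camera adjusted p 0.0383), namely the cyclins Ccnd1 at 1.12, Ccnd2 at 0.60 and Ccne1 at 1.05 and the replication helicase subunit Mcm4 at 1.01 in the authors' deposited table. The Wnt list was lower than the other targets by camera (adjusted p 0.0162). Of its 42 targets 18 were positive and 24 negative, with a median log2 fold change of −0.1 in the authors' deposited table. In this list 1 target rose, Ccnd1, and 3 fell, Lgr5, Fzd9 and Tcf7l1 (1 and 2 adjusted over the list alone). Tcf7l1 encodes a repressor of Wnt target genes. The Notch list had 2 of 19 fallen, Hes1 and Lfng (0 adjusted over the list alone, camera adjusted p 0.111), and the MAPK and growth factor list 2 of 30 risen, the phosphatases Dusp5 and Dusp6, and 2 fallen, Fgfr3 and the growth factor Egf (1 and 2 adjusted over the list alone, camera adjusted p 0.692). Single targets fell in the lists for cell cycle inhibitors (Cdkn1c, 1 of 18, camera adjusted p 0.284) and DNA repair (Mgmt, 1 of 35, 0.235), and in both 0 fell adjusted over the list alone. None of 27 TGF-beta and BMP, 10 iron or 7 autophagy targets passed (camera adjusted p 0.32, 0.118 and 0.692). Among structural markers, Vcam1, an adhesion molecule that cytokines induce, was the 1 of 9 endothelial targets that rose (camera adjusted p 0.744), none of 10 fibroblast and muscle targets passed (0.854), and none of 4 reference genes did (0.692).

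**Figure D2:**
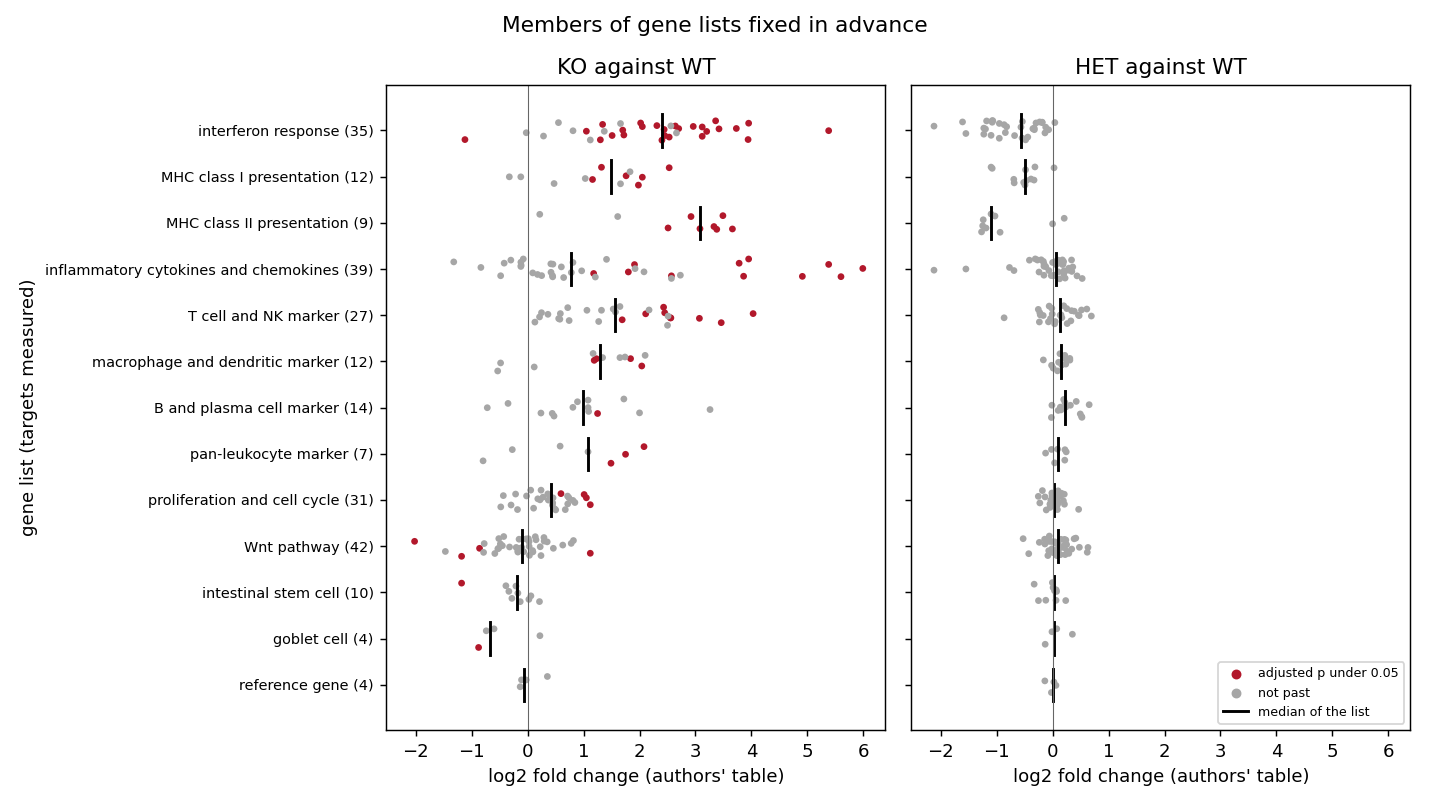
Log2 fold change of each measured target (points) by fixed gene list in KO against WT and HET against WT, with list medians marked. The interferon response list has a median of 2.40 in KO and −0.57 in HET.

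Of the 13 lists that passed in KO, 4 pass at a preset correlation of 0.05, the interferon response, MHC class I, MHC class II, and T cell and NK lists, and 0 at 0.5. After centring on the median the NF-kB, JAK-STAT and proliferation lists no longer pass (adjusted p 0.0548, 0.0851 and 0.0695). Centring also lowers the number of risen members, from 25 to 17 in the interferon response list, 7 to 3 in inflammasome and cell death, 5 to 3 in NF-kB, 5 to 2 in JAK-STAT, 4 to 2 in macrophage and dendritic, 4 to 1 in proliferation, and 2 to 0 in MAPK and growth factor. It raises the number of fallen members from 1 to 3 in DNA repair and from 1 to 2 in the goblet cell list. The test's sign and the list's median or mean differ for 7 lists in KO, none of which passed.

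The comparison of HET with WT asks whether losing a single copy of Ptpn2 has an effect. No target passed. Interferon-induced and antigen-presentation targets had negative fold changes as a set, opposite in sign to KO.

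With the authors' p-values 0 of 1398 targets passed, also 0 with limma's moderated standard errors, and 18 had an unadjusted p under 0.05 (6 higher, 12 lower) where chance gives 69.9. The 2 lower targets with the smallest p were Ciita, at −0.94 (SE 0.28, p 0.0129), and Cxcl10, at −2.12 (SE 0.66, p 0.0154), and the 2 higher ones were Cxxc4, a Wnt antagonist, at 0.87 (p 0.0141) and Dtx1, a Notch regulator, at 1.12 (p 0.0146), on the log2 scale of the authors' deposited table. None of them is past the threshold (adjusted p 1). Of the 35 interferon response targets 34 were negative, with a median log2 fold change of −0.57 in the authors' deposited table and a camera adjusted p of 5.92e-18. The MHC class I list had 11 of 12 targets negative (median −0.49 in the authors' deposited table, camera adjusted p 1.74e-10), and the MHC class II list 8 of 9 (median −1.10 in the authors' deposited table, camera adjusted p 1.54e-09). Adjusted over the list alone, 0 members passed in these 3 lists. All 3 pass at a preset correlation of 0.05 and none at 0.5, where the adjusted p is 0.119, 0.0693 and 0.0693. Camera sets the shift of a list against the spread over all targets, which was small in HET. There the variance of the fold change over its standard error was 0.74 among loglinear and lm.nb targets. In KO it was 6.69 over all targets. List p-values in HET are thus smaller for the same shift in z and cannot be ranked against those in KO. No other list passed, the leukocyte marker lists included, but with the log2 fold change as camera's statistic the B and plasma cell list (adjusted p 0.016) and the fibroblast and muscle list (adjusted p 0.0303) were higher in HET.

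The comparison of KO with HET, computed here from the authors' deposited table, asks what the loss of the remaining copy changes. Of the 155 targets that were higher in KO than in WT, 136 were higher than in HET as well, while Ptprc, Mrc1, Tyrobp and Nfkb2 are among those that did not pass here. Lgr5, Dclk1 and Fgfr3 were again lower, and Muc2 and Spdef, which missed the threshold against WT, were past it here.

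In KO against HET, 172 targets rose and 66 fell (150 and 88 after centring on the median). Of the 155 that rose against WT 136 rose here, and of the 45 that fell 40 fell. Both comparisons use the same KO mice, so the overlap is not independent evidence. Ccl8, Gzma, Ccl5 and Ciita had the smallest adjusted p, 0.00152 each, with log2 differences from the authors' deposited table of 5.68, 4.90, 3.76 and 3.45. Among risen targets B2m had the next smallest unadjusted p, with a log2 difference of 2.67. Among the fallen, Fgfr3 changed by −1.78 and Lgr5 by −1.24 (adjusted p 0.00301 each), Stk26 by −1.75 and Creb3l4, a transcription factor of secretory cells, by −0.96 on the log2 scale, computed from the authors' deposited table. Of the 35 interferon response targets 32 rose and 1 fell (33 and 1 adjusted over the list alone, camera adjusted p 1.89e-12). The MHC class I list had 8 of 12 risen (10 adjusted over the list alone, camera adjusted p 7.52e-05), and the MHC class II list 7 of 9 (8 adjusted over the list alone, 1.48e-05). T cell and NK markers had 9 of 27 risen, also adjusted over the list alone (camera adjusted p 0.000192), and the macrophage and dendritic list 3 of 12 (4 adjusted over the list alone, 0.066). Cytokines and chemokines had 11 risen and 1 fallen of 39 (12 and 1 adjusted over the list alone, camera adjusted p 0.0208), and the NF-kB list 6 and 1 of 26 (10 and 1 adjusted over the list alone, 0.0191). JAK-STAT had 5 of 26 risen (camera adjusted p 0.0209), and the IL-6, IL-22 and STAT3 list 4 of 12 (0.0208), with as many adjusted over the list alone. The Wnt list was lower than the other targets, with 2 risen and 4 fallen of 42, also adjusted over the list alone (camera adjusted p 0.0041). Of the 4 goblet targets 3 fell, Atoh1, Muc2 and Spdef, without the list passing (1 rose and 3 fell adjusted over the list alone, 0.0582), and the stem cell list did not pass (0.0642). Of these 9 lists, 4 pass at a preset correlation of 0.05 and 0 at 0.5.

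**Figure D3:**
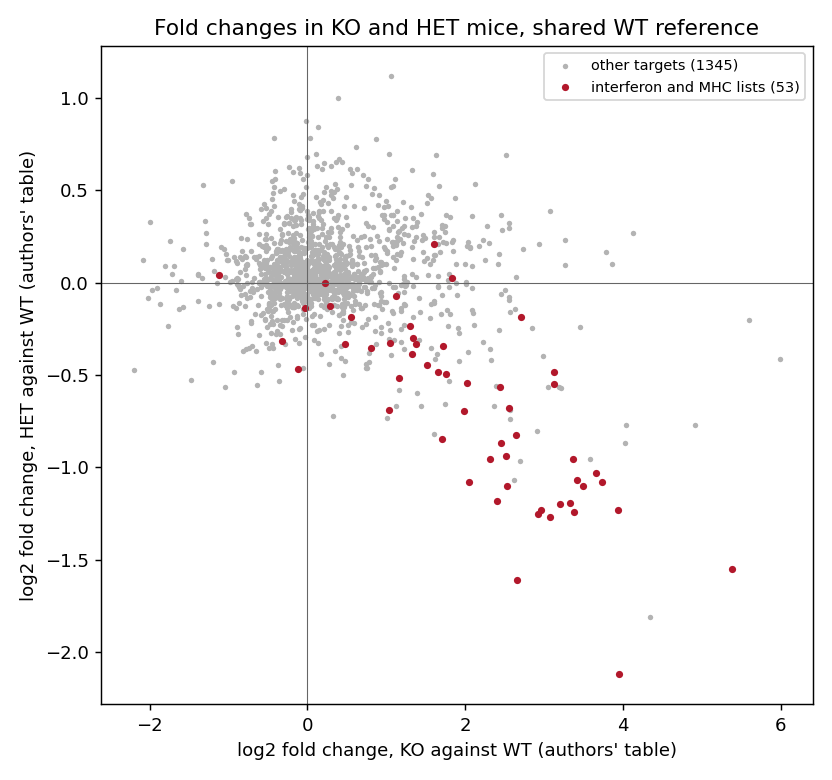
Log2 fold change of KO against WT (horizontal axis) and HET against WT (vertical axis) for 1398 targets, with interferon and MHC targets marked. Across targets Pearson's r is −0.324 and Spearman's rho −0.06.

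Across the 1398 targets the KO and HET fold changes had Pearson's r of −0.324 and Spearman's rho of −0.06, and targets are not independent replicates. Both fold changes share the WT mice, which pushes r upward. In 1000 simulated sets neither genotype changed and targets were drawn independently. There r averaged 0.494, with 95% of sets between 0.317 and 0.655. Targets that vary together would widen the simulated ranges, so these do not test r or the covariance. The averages are limited as well. The sets hold no KO change, which makes their r too high as a reference. Their spread comes from the standard errors, while HET varied less than those give (variance 0.74 against 1.4 among loglinear and lm.nb targets). The covariance was −0.0913, where the simulated sets averaged 0.0971 (95% of sets between 0.0539 and 0.1606). Without Wald targets it was −0.0988, where the sets averaged 0.0608. Without the interferon and MHC lists the covariance was −0.0252, where 95% of sets lay between 0.0521 and 0.1624. Leaving out those lists does not remove every interferon-induced target. Ifi44l, at 4.34 in KO and −1.81 in HET in the authors' deposited table, is in none of them. Of the 155 targets that rose in KO, 101 had a negative fold change in HET, and of the 45 that fell in KO, 17 did. Over all targets 562 were negative in HET, which for independent lists would give 62.3 and 18.1. These counts were not tested, since the shared WT mice alone tie the signs together, toward the same sign. Splitting the WT mice was not possible without values per mouse.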

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

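All alternatives were chosen after seeing the data, except the minimum log2 fold change of 1. In KO against WT the main count was 200 targets, which became 3 by Benjamini-Yekutieli, 6 by Bonferroni, 309 with moderated standard errors and 498 with unadjusted p. In KO against HET the count was 238, which became 38 by Benjamini-Yekutieli, 16 by Bonferroni and 489 with unadjusted p. In HET against WT the count was 0, and 18 with unadjusted p. The adjustments differ by construction in how strict they are. With a minimum log2 fold change of 1, without Wald targets, with 1 probe per gene or centred on the median, the total counts stayed within 1.5 times those values. The split by direction moved more: with the minimum of 1 the fallen targets went from 45 to 22 in KO against WT and from 66 to 31 in KO against HET, and with centring the 155 risen and 45 fallen of KO against WT became 103 and 75.

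Of 13 lists in KO against WT, 4 passed at a preset correlation of 0.05, 0 at 0.5 and 7 with the log2 fold change as the statistic. Of 9 lists in KO against HET, 4 passed at 0.05 and 0 at 0.5. The 3 lists lower in HET against WT did not pass at 0.5, which left 0. With the log2 fold change as the statistic 5 passed, those 3 and the B and plasma cell and fibroblast and muscle lists, which were higher. A higher preset correlation widens the test by construction, and the cause of the other shifts was not tested. The true correlation between targets is unknown here, and targets under shared control by interferon are those for which a high value is most plausible.

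The covariance of the KO and HET fold changes moved from −0.0913 to −0.0252 without the interferon and MHC lists and was −0.0988 without Wald targets and −0.0899 with 1 probe per gene. Spearman's rho changed sign, from −0.06 to 0.021, without the interferon and MHC lists. No count, named target or list that passed reversed its direction. Of the 83 named targets in KO against WT, 13 lost their call when centred and 4 with 1 probe per gene, where Il4ra, Tyrobp, Dusp6 and Hes1 lie at the threshold.

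No paired analysis was possible because no value column is assigned to a mouse, and so to a littermate group. Because no value column is assigned to a mouse, these settings, written down before the data were examined, were not run: fits of 2 genotypes, littermate and sex terms, females alone, the pseudocount, the low-value filter, other normalisations, other variance models, estimated correlation, fry, the split of WT mice, and leaving out each mouse. The settings for Ptpn2, which is not analysed here, were not run either. Whether a single mouse decides a result is therefore open.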

Other observations

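The groups of targets in the first paragraphs were picked after their values were seen, so their members are counted and no test of a group as a set is given. The tests on MHC class II, stem cell and HET further on concern patterns seen in these data. Only their predictions were written before those tests were run. Complement genes encode plasma proteins that tag and lyse microbes. Of 17 complement components 8 rose in KO against WT and none fell. Among them were C1s1 at 3.19 and C2 at 3.58 of the early classical pathway and the shared component C3 at 2.22. Cfb rose by 0.86, all on the log2 scale of the authors' deposited table. Macrophages make C1qa and C1qb, which were already counted among leukocyte markers. Against HET, 8 complement components rose as well.

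Some adhesion and chromatin genes changed in KO against WT as well. Of 6 laminin chains 2 rose and none fell. Of 17 integrin chains 5 rose, the epithelial Itgb6 at 1.14 and Itga3 at 0.94 among them in the authors' deposited table, together with the leukocyte chains Itgal and Itgb2. Of 7 histone deacetylases Hdac11 and Hdac5 fell by 1.38 and 0.86 on the log2 scale of the authors' deposited table. In the CREB family of 8, Creb3l3 rose by 2.55 while the secretory cell factors Creb3l4 and Creb3l1 fell by 0.83 and 0.53 on the log2 scale of the authors' deposited table. None of 4 haemoglobin chains, whose paralogs share sequence and which mark red blood cells, passed in any comparison. All 4 were positive in KO against WT (median log2 fold change 1.25 in the authors' deposited table) and all 4 negative in HET against WT (median −0.63 in the authors' deposited table).

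MHC class II targets were higher in KO, and a candidate explanation is a larger share of antigen-presenting leukocytes in the preparation, for which the protocols describe no removing sort. The prediction for that as the whole cause was a class II list that rises no more than macrophage, dendritic and B cell markers. Its mean log2 fold change exceeded theirs by 1.66 (2-sided permutation p 0.00022). The permutation takes targets as independent, while targets under shared control move together. Log2 fold changes also depend on the level of each target, so the test does not decide. None of the 9 class II targets belongs to another list, though macrophages and B cells express them too. The means were 2.69 for class II and 1.03 for the leukocyte markers, and absolute levels are not used here. A larger share of antigen-presenting leukocytes, activated leukocytes with more MHC class II per cell, and induction in epithelial cells all stay open.

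The stem cell list was lower in KO against WT by camera, which dilution by other cells could give, but the pattern is weak: only Lgr5 of its 10 targets passed, and the list did not pass at a preset correlation of 0.05 (adjusted p 0.0877) or against HET (0.0642). With dilution, general epithelial targets would fall as much. The stem list's mean lay below theirs by a log2 difference of −0.29 (exact 2-sided permutation p 0.343), which does not decide between them. Of the 3 epithelial targets, Vil1 and Cdh1 had positive log2 fold changes, 0.50 and 0.38, and Muc2, a goblet cell mucin, −0.74 in the authors' deposited table. Only Vil1 passed, and it lost its call after centring on the median, so these 3 targets do not decide either. Dilution, a change in the cells' own expression and a loss of stem cells stay open.

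HET against WT gave fewer small p-values than chance, 18 where 69.9 would be found. Noise at targets near background may give this. Among loglinear and lm.nb targets the variance of the HET fold change over its standard error was 0.74, below the 1.4 that the t distribution gives, but the kind of regression does not measure the distance from background, so that explanation stays open. A spread shared with the KO mice predicts a ratio of variances under 1 between the targets with the largest and the smallest KO change. The ratio was 1.3, on the other side of 1 but not beyond its spread (2-sided permutation p 0.0519), so it was not excluded. All 298 loglinear targets have equal standard errors in both deposited tables, so for them the spread is shared. Whether that sharing or the unknown terms of the authors' model give the pattern stays open, so a lack of calls in HET does not show an absence of change.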
